A study of Bos taurus with 16 samples.

How the data were processed

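Liver gene expression was measured in 16 Angus steers with 1 array per animal, 8 steers sampled at the end of a growing phase and 8 at the end of a finishing phase. Per the labels, total RNA was extracted with Trizol, converted to biotin-labelled cRNA and prepared by the Affymetrix protocol for arrays. The submitters' processing notes name GCOS 1.2 and Partek 6.4 without giving their roles. The method that summarised probes into probe sets and normalised the arrays is not given in the sources used here.

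The deposited values are log2 signals per probe set, as inferred from their range of 1.48 to 14.1, and were used as deposited, without further normalisation or filtering. Array medians lay between 5.57 and 5.64, so the deposited arrays were already on a common scale. The table holds no detection calls, so dim probe sets were not removed in the main comparison, and a change near the lower end of the scale may be compressed. The number of arrays limits the precision, and no scan date or hybridisation batch was used here. Groups came from the sample labels. Each steer is a separate animal, and no pair of arrays held identical values.

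Of 26773 probe sets, 18457 carried 1 gene symbol in the platform annotation, 688 carried several and 7628 were unnamed here. The labels describe oligo(dT)-primed cRNA labelling, whereas the platform annotation appears to be that of a gene array, and the sources used here do not settle which array was hybridised. Every gene name rests on that annotation. Under it the liver transcripts ALB and TTR had growing means of 13.7 and 13.1, while APOA1, also abundant in liver, had 6.62, so single assignments may be wrong. Control probe sets could not be told apart among the unnamed ones, and all were kept. Of the probe sets with 1 symbol, 17996 matched by gene identifier to the RefSeq gene table of assembly ARS-UCD2.0, which changed 0 symbols and was used for names only. Each of the 18010 named genes was represented by its probe set with the highest mean, and 401 genes had over 1 probe set.

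Differential expression was tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes without a trend, 2-sided), finishing minus growing, with Benjamini-Hochberg adjustment over all probe sets and a threshold of 0.05. Errors of differences are standard errors from this fit. Gene lists were tested with limma's camera at a preset inter-gene correlation of 0.01, 2-sided, adjusted over 48 lists with at least 5 measured members. The lists cover hepatic metabolism, growth signalling, proliferation, stress, immunity, zonation and cell types, and share some genes. Of their 1034 symbols 896 were measured, 24 through an older symbol. Members are counted past the threshold over all probe sets and adjusted over the list alone. A list score is the mean log2 signal of the measured members in an array. Scores were compared between groups by a 2-sided exact permutation test over 12870 arrangements, adjusted over the 48 lists. It asks whether a list differs between groups, not whether it differs from other genes. This score test was added after the camera results had been seen, as were its repeats without finishing replicates 5 and 6, without growing replicate 4, and for cell cycle genes without each array.

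The lists, the tests and the rule for named genes were fixed before the data were examined. The rule takes the 10 largest rises and 10 largest falls among genes past the threshold whose mean in the higher group exceeds the median probe set mean of 5.595. It adds up to 4 members per list with the smallest p among those past the threshold. SLC1A1, SLC1A2, GLUL, ARL6IP5, IGF1 and GHR are taken whatever their p, and so are the 3 brightest members of each cell type list past camera. Symbols of uncharacterised loci were not named. GLUL was not analysed here. Where a gene outside the rule is named, the text says so.

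The alternatives were quantile normalisation, centring on the array median or on ribosomal protein genes, a variance trend with robust estimation, array weights, filters on dim probe sets, averaging a gene's probe sets or taking the most variable one, stricter thresholds, a rank-sum test, a replicate block, an estimated inter-gene correlation, limma's fry, and leaving out each array in turn. An alternative pseudocount did not apply to log2 values. Leaving out finishing replicates 5 and 6 together, and testing annotated probe sets only, were added after seeing the data.

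The fit was tested on simulated data drawn from the real means and spreads of the 26773 probe sets, with 200 probe sets changed between 8 and 8 simulated arrays. Of those changed by a log2 difference of 0.5, a median of 65.6% (59.2% to 75.4% over 20 simulations) were recovered, against 95.7% (91.2% to 100%) at 1 and 100% (97.1% to 100%) at 2. False calls numbered 4 to 16, with a median of 9, among 171 to 195 calls. Camera called the 1 shifted list in every simulation and 0 to 1 other lists. Simulated genes varied independently, so this says nothing about camera where genes vary together. Both simulated groups were drawn with the same spread for a probe set. The recovery and false calls therefore do not cover genes whose spread differs between groups, such as SERPINI2 (SD 0.17 in growing and 2.02 in finishing steers).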

Results

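Weaned Angus steers with a starting body weight of 209 ± 29.4 kg were assigned at random to a growing phase, ending at 301 kg, or a finishing phase, ending at 576 kg. All were fed individually on a cotton seed hull diet for a constant gain of 1.5 kg per day. Liver RNA from 8 steers per phase was measured on 16 arrays, giving log2 signals for 26773 probe sets. Correlations between arrays ran from 0.982 to 0.990 among growing steers, from 0.974 to 0.988 among finishing steers, and from 0.968 to 0.987 between phases. The comparison asks how hepatic expression differs between steers at the end of finishing and steers at the end of growing. Body weight, age and time on feed differ together between the groups. Sampling date was not used here and may differ with them. The arrays limit precision through their number, with a median within-group SD of 0.192 on the log2 scale.

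**Figure D1:**
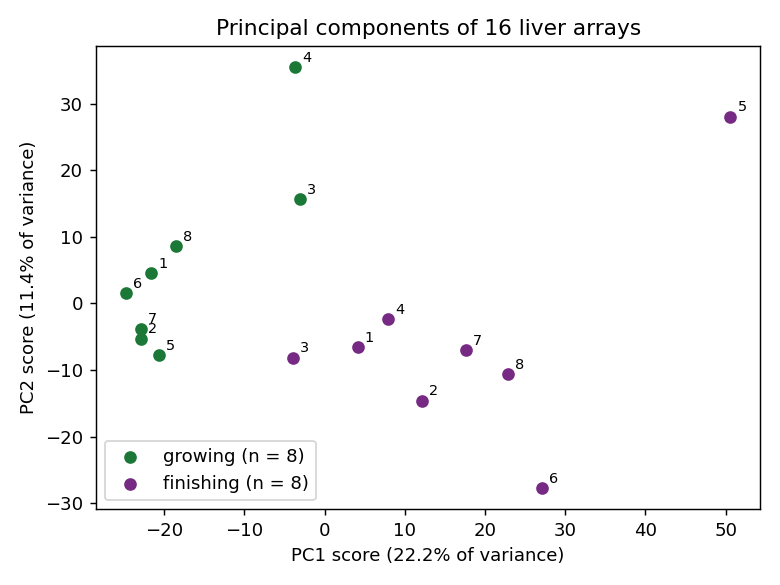
Principal component scores of the 16 arrays over all probe sets, with PC1 (22.2% of the variance) on the horizontal axis and PC2 (11.4%) on the vertical axis, each point a steer labelled with its replicate number. Finishing replicate 5 has the highest PC1 score, 50.57, and finishing replicate 6 the next, 27.1.

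Among the largest rises in finishing livers were SDS, an enzyme of amino acid degradation, and the citrate transporter SLC13A5. Among the largest falls were SULT1E1, SOCS2, FADS1 and the cell division genes MKI67 and CENPF. By limma, 626 probe sets were higher and 1151 lower in finishing steers, together 6.64% of those tested. They represent 486 genes that rose and 1019 that fell, 1 probe set per gene. The median change among called probe sets was 0.445 upward and -0.44 downward on the log2 scale, and 47 rose and 45 fell at least 2-fold. Without finishing replicates 5 and 6, which correlated least with their own group (medians 0.978 and 0.982), 288 were higher and 654 lower. Leaving out growing replicate 1 or 8 alone gave 410 or 415 higher.

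SDS, serine dehydratase, rose by 2.48 ± 0.35 on the log2 scale (SE, n = 8 per group; 5.58-fold; adjusted p = 0.0013), and 7 of 8 finishing steers lay above all growing steers. SLC13A5, the plasma membrane citrate transporter, rose by 2.18 ± 0.33 (4.53-fold, adjusted p = 0.00173), with all 8 finishing steers above all growing steers. SLC5A8, a monocarboxylate transporter, rose by 2.38 ± 0.47 (adjusted p = 0.00734). PCDH19, a protocadherin, rose by 2.13 ± 0.30 and APOA4, an apolipoprotein, by 1.98 ± 0.28 (both adjusted p = 0.0013). GNMT, glycine N-methyltransferase, rose by 1.85 ± 0.32 (adjusted p = 0.00366), and FAM107A by 1.77 ± 0.30 (adjusted p = 0.00316). SERPINI2, a serpin, had the largest mean rise, 3.00 ± 0.65 (adjusted p = 0.0117), but was uneven, at 3.30 and 3.01 in finishing replicates 5 and 7 and between 4.93 and 8.99 in the others, against 2.86 ± 0.17 (SD) in growing steers. OAT, ornithine aminotransferase, rose by 1.93 ± 0.51 (adjusted p = 0.0306), and LPIN1, a phosphatidate phosphatase, by 1.70 ± 0.44 (adjusted p = 0.0261). The OAT call was lost in 7 of 16 fits that left out 1 array (growing replicates 1, 2, 6 and 8 and finishing replicates 6, 7 and 8), with a highest adjusted p of 0.0622. That of LPIN1 was lost in 6 (growing replicates 1 and 8 and finishing replicates 5, 6, 7 and 8), with a highest adjusted p of 0.0543.

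SULT1E1, estrogen sulfotransferase, fell by 2.91 ± 0.54 (SE, n = 8 per group; adjusted p = 0.00504), with growing steers spread from 4.87 to 9.40. FADS1, a fatty acid desaturase, fell by 1.44 ± 0.19 (adjusted p = 0.000996). SOCS2, a growth hormone induced suppressor of cytokine signalling, fell by 1.64 ± 0.26 (adjusted p = 0.00209). The proliferation marker MKI67 fell by 1.32 ± 0.22 (adjusted p = 0.00303), the kinetochore gene CENPF by 1.31 ± 0.23 (adjusted p = 0.0042) and CKAP2, a spindle-associated gene, by 1.21 ± 0.17 (adjusted p = 0.0013). For MKI67 and CKAP2 all 8 finishing steers lay below all growing steers. IFI6, an interferon-induced gene, fell by 1.27 ± 0.25 (adjusted p = 0.00763), the sterol exporter ABCG8 by 1.26 ± 0.30 (adjusted p = 0.0189) and the receptor ERBB3 by 1.24 ± 0.28 (adjusted p = 0.0152). LYZ, lysozyme, fell by 1.27 ± 0.37 (adjusted p = 0.0464). The LYZ call was lost in 11 of 16 fits that left out 1 array (growing replicates 1, 4, 6, 7 and 8 and finishing replicates 2, 3, 5, 6, 7 and 8), with a highest adjusted p of 0.0876. Without finishing replicates 5 and 6 ABCG8 had an adjusted p of 0.0644.

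**Figure D2:**
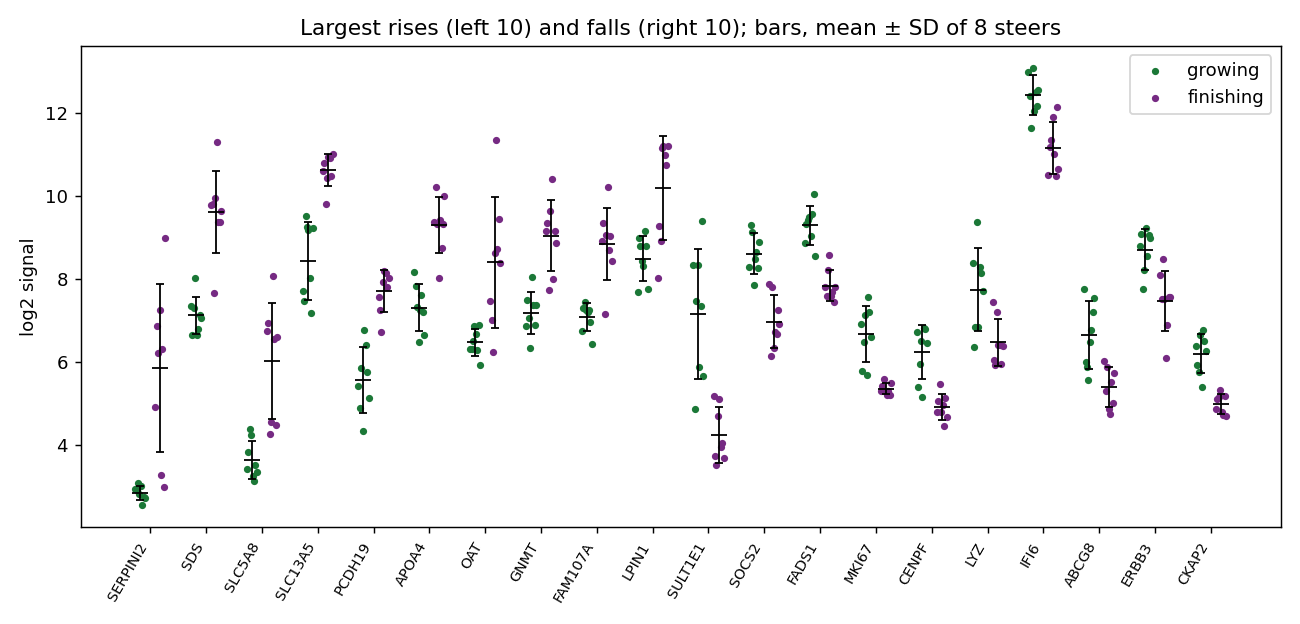
Log2 signal of the 10 genes with the largest rises and the 10 with the largest falls, each point a steer and bars the mean ± SD of 8 steers per group. SLC13A5 separates the groups completely upward and MKI67 and CKAP2 completely downward, while SERPINI2 ranges from 3.01 to 8.99 in finishing steers.

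Of the 48 gene lists, 16 passed camera with the preset correlation, 6 upward and 10 downward. With an estimated correlation 1 list passed, the stellate cell and fibroblast markers. Regrouped arrays also gave many list calls: 7 of 100 splits of the 16 arrays, the real one included, gave 16 lists or more. For each of the 16 lists the estimated-correlation value and an exact permutation p of the list score, adjusted over 48 lists, are given as well. Limma's fry passed 13 lists. Of the 16, amino acid catabolism (adjusted p = 0.0996), cholesterol synthesis (0.162), the unfolded protein response (0.239) and endothelial markers (0.0995) did not pass fry, and B and plasma cell markers passed fry without passing camera (0.0249).

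Markers of stellate cells and fibroblasts, the matrix-producing cells of liver, were lower in finishing steers, as were extracellular matrix genes. In the stellate and fibroblast list 9 of 15 measured members fell and 0 rose (12 and 0 adjusted over the list alone), with a median change of -0.41. LRAT, the retinol esterifying enzyme, fell by 1.08 ± 0.14 and COL3A1, a collagen, by 0.73 ± 0.10 (both adjusted p = 0.000996), and COL1A1 by 0.86 ± 0.13 (adjusted p = 0.00174). DCN, decorin, fell by 0.41 ± 0.06 (adjusted p = 0.00205). The list's camera adjusted p was 4.28e-10, with adjusted p = 0.00575 with an estimated correlation and an exact permutation adjusted p of 0.00249. In the extracellular matrix list 17 of 34 fell and 1 rose (20 and 2 adjusted over the list alone), with a median of -0.29. LUM, lumican, fell by 0.97 ± 0.10 (adjusted p = 0.000189), SPARC, a matrix-associated glycoprotein, by 0.82 ± 0.08 (adjusted p = 0.000134) and TGFBI by 0.58 ± 0.08 (adjusted p = 0.000996). The matrix list gave a camera adjusted p of 5.51e-13, adjusted p = 0.0546 with an estimated correlation, and an exact permutation adjusted p of 0.00249. For SPARC, LUM, COL3A1, COL1A1, LRAT, TGFBI and DCN all 8 finishing steers lay below all growing steers.

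Cell cycle genes were lower in finishing steers. Of 35 measured members 18 fell and 0 rose (23 and 2 adjusted over the list alone), with a median of -0.41. CCNA2, cyclin A, fell by 1.14 ± 0.16 (adjusted p = 0.00146), KIF20A, a mitotic kinesin, by 1.06 ± 0.17 (adjusted p = 0.00268) and AURKB, a mitotic kinase, by 0.70 ± 0.10 (adjusted p = 0.00105). The camera adjusted p was 6.08e-11, with adjusted p = 0.179 with an estimated correlation and an exact permutation adjusted p of 0.00249. Alongside, the score of T and NK lymphocyte markers differed by -0.38 ± 0.11 (SE). Of the cell cycle arrest list 1 of 12 members rose and 1 fell, against 2 and 2 adjusted over the list alone (camera adjusted p = 0.617). LMNB1, lamin B, fell by 0.65 ± 0.10 (adjusted p = 0.00209). CDKN1A rose by 0.92 ± 0.27 (adjusted p = 0.0481), a call lost in 11 of 16 fits that left out 1 array. Camera tests a shift shared in 1 direction, so it does not show whether members that moved in opposite directions belong together.

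Markers of T and NK lymphocytes and of macrophages, MHC class II genes and interferon response genes were lower in finishing steers, while neutrophil markers (0 of 14 past the threshold, median 0.024) did not pass camera. Neutrophil scores averaged 4.86 in growing and 4.90 in finishing steers, below the median probe set mean of 5.595. Without detection calls, undetected neutrophil transcripts cannot be told apart from unchanged ones. B and plasma cell markers passed fry downward (adjusted p = 0.0249) but not camera (adjusted p = 0.0551). Growing replicate 4 had the highest macrophage score (9.36) and MHC class II score (7.52) of the 16 arrays and the highest PC2 score (35.49). Without it the 4 list scores still differed, by -0.33, -0.34, -0.238 and -0.485 in the order named (exact permutation p = 0.00948, 0.0194, 0.0121 and 0.0137). The interferon score was uneven among growing steers and highest in replicates 1, 4 and 8 (7.926, 7.699 and 7.605). Growing replicates 2, 3, 5 and 6 (7.138, 6.878, 6.978 and 6.922) lay within the finishing range of 6.445 to 7.229. Among T and NK lymphocyte markers 7 of 19 fell and 0 rose (11 and 0 adjusted over the list alone), including CD3D by 0.96 ± 0.17 (adjusted p = 0.00462) and CD3E by 0.74 ± 0.13 (adjusted p = 0.00473), both parts of the T cell receptor complex. The brightest other members, IL7R and NKG7, had differences of -0.13 (adjusted p = 0.783) and -0.41 (adjusted p = 0.0765, and 0.0348 without growing replicate 3 or 0.0363 without finishing replicate 3). The camera adjusted p was 2.4e-06, with adjusted p = 0.433 with an estimated correlation and an exact permutation adjusted p of 0.0205. Among Kupffer cell and macrophage markers 8 of 17 fell and 0 rose (12 and 0 adjusted over the list alone), including CSF1R, the macrophage growth factor receptor, by 0.72 ± 0.14 (adjusted p = 0.00763) and TIMD4 by 0.71 ± 0.17 (adjusted p = 0.0174, and 0.0607 without finishing replicates 5 and 6). The brightest members, C1QB, C1QC and CD5L, had differences of -0.38, -0.47 and -0.098 (adjusted p = 0.0657, 0.0742 and 0.669), and without finishing replicate 4 C1QB and C1QC passed (adjusted p = 0.027 and 0.0301). The camera adjusted p was 2.4e-06, with adjusted p = 0.433 with an estimated correlation and an exact permutation adjusted p of 0.0294. In the MHC class II list 5 of 12 fell and 0 rose (6 and 0 adjusted over the list alone), with CD74, the invariant chain, down in all 8 finishing steers below all growing steers (-0.62 ± 0.10, adjusted p = 0.00249). That list gave a camera adjusted p of 0.000137, adjusted p = 0.285 with an estimated correlation, and an exact permutation adjusted p of 0.0224. In the interferon list 7 of 24 fell and 0 rose (16 and 0 adjusted over the list alone), with a median of -0.54 and PSMB8, an immunoproteasome subunit, lower by -0.69 ± 0.13 (adjusted p = 0.00503). Its camera adjusted p was 6.53e-07, with adjusted p = 0.433 with an estimated correlation and an exact permutation adjusted p of 0.0261.

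Chemokine and endothelial lists lay near the threshold. Of 23 NF-kB and chemokine genes 4 fell and 0 rose (4 and 0 adjusted over the list alone), including CCL21 by 0.55 ± 0.12 (adjusted p = 0.0131) and CCL5 by 0.51 ± 0.11 (adjusted p = 0.0134). The camera adjusted p was 0.0493, with adjusted p = 0.503 with an estimated correlation and an exact permutation adjusted p of 0.0385, and the camera call was lost in 8 of 16 fits that left out 1 array (growing replicates 3 and 4 and finishing replicates 1, 2, 3, 6, 7 and 8), with adjusted p from 0.0148 to 0.164 over all 16. Of 17 endothelial markers PECAM1 and CDH5, both junction proteins, fell by 0.34 ± 0.08 and 0.38 ± 0.10 (adjusted p = 0.0226 and 0.0238, and 0.0733 for CDH5 without finishing replicates 5 and 6) and 0 rose (5 and 0 adjusted over the list alone). LYVE1, ENG and OIT3, the brightest, had differences of 0.061, -0.22 and -0.19 (adjusted p = 0.77, 0.11 and 0.284). The endothelial camera adjusted p was 0.0493, with adjusted p = 0.646 with an estimated correlation and an exact permutation adjusted p of 0.0534, and the camera call was lost in 9 of 16 such fits (growing replicates 2, 3, 4, 5 and 8 and finishing replicates 1, 2, 3 and 7), with adjusted p from 0.0112 to 0.13 over all 16.

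The growth hormone receptor and several of its axis genes were lower in finishing steers, and IGF1 did not pass the test. In the somatotropic axis 6 of 19 members fell and 1 rose (7 and 1 adjusted over the list alone), with a median of -0.17. GHR, the growth hormone receptor, fell by 0.38 ± 0.08 (adjusted p = 0.0128), IGFBP5 by 0.47 ± 0.09 (adjusted p = 0.00475) and IGFBP7 by 0.37 ± 0.07 (adjusted p = 0.00605), both binding proteins. IGF1 was 10.3 ± 0.20 in growing and 10.1 ± 0.37 in finishing steers (SD, n = 8 per group), a difference of -0.17 ± 0.14 (SE, adjusted p = 0.523 by limma). Without finishing replicates 5 and 6 the IGF1 difference was -0.34 (adjusted p = 0.0749), and leaving out 1 array at a time gave adjusted p from 0.143 to 0.684. The camera adjusted p was 0.00035, with adjusted p = 0.0811 with an estimated correlation and an exact permutation adjusted p of 0.00597.

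Periportal, urea cycle and glucocorticoid responsive genes were higher on average in finishing steers. Amino acid catabolism genes were higher by some tests and not by others. In the periportal list 5 of 13 members rose and 1 fell (7 and 1 adjusted over the list alone), with GLS2, liver glutaminase, up by 0.997 ± 0.17 (adjusted p = 0.00403), SLC25A15, the mitochondrial ornithine carrier, up by 1.18 ± 0.24 (adjusted p = 0.00775), and GLUD1, glutamate dehydrogenase, down (-0.45 ± 0.08, adjusted p = 0.00316). The median change was 0.23, well below the mean of 0.576, to which SDS contributed most. Its camera adjusted p was 0.000149, with adjusted p = 0.315 with an estimated correlation and an exact permutation adjusted p of 0.00559. In the amino acid catabolism list 7 of 31 rose and 3 fell (8 and 3 adjusted over the list alone), led by SDS and GNMT, with a median of 0.11 and a mean of 0.307. KYNU, kynureninase, and PRODH2, which degrades hydroxyproline, went the other way, by -0.63 ± 0.11 (adjusted p = 0.00458) and -0.53 ± 0.11 (adjusted p = 0.0101). The list's camera adjusted p was 0.0151, with adjusted p = 0.646 with an estimated correlation and an exact permutation adjusted p of 0.00995, against 0.0996 by fry, and the camera call was lost without growing replicate 3 (adjusted p = 0.068) or growing replicate 4 (adjusted p = 0.0676). Of 10 urea cycle genes 2 rose, SLC25A15 and ASS1, both also in the periportal list, and 0 fell (5 and 0 adjusted over the list alone). ASS1 rose by 0.22 ± 0.06 (adjusted p = 0.0436), and its call was lost in 11 of 16 fits that left out 1 array (highest adjusted p = 0.0837). The urea cycle list gave a camera adjusted p of 0.00354, adjusted p = 0.433 with an estimated correlation, and an exact permutation adjusted p of 0.0149. Of 16 glucocorticoid responsive genes 3 rose and 0 fell (4 and 0 adjusted over the list alone), among them ANGPTL4, a lipase inhibitor, by 1.13 ± 0.31 (adjusted p = 0.0356). The ANGPTL4 call was lost in 8 of 16 fits that left out 1 array (growing replicates 1, 2, 5, 6, 7 and 8 and finishing replicates 6 and 8), with a highest adjusted p of 0.0721. TAT and CDKN1A, the other risers (adjusted p = 0.0474 and 0.0481), lost the call in 13 and 11 of these fits. Without finishing replicates 5 and 6 none of the 3 passed (adjusted p = 0.0833, 0.137 and 0.156, ANGPTL4 first). That list gave a camera adjusted p of 0.00592, adjusted p = 0.433 with an estimated correlation, and an exact permutation adjusted p of 0.0294. Its score was uneven among finishing steers. Replicates 1, 2, 3 and 4 (9.43, 9.45, 9.422 and 9.196) lay within the growing range of 8.932 to 9.554. Finishing replicates 5, 6, 7 and 8 lay above it (10.058, 9.942, 9.63 and 9.949).

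Cholesterol synthesis and protein folding lists were higher in camera alone. Of 16 cholesterol genes 2 rose and 0 fell (4 and 0 adjusted over the list alone), MVK, mevalonate kinase, by 0.78 ± 0.16 (adjusted p = 0.00839) and CYP51A1 by 0.74 ± 0.20 (adjusted p = 0.0332). The CYP51A1 call was lost in 9 of 16 fits that left out 1 array (highest adjusted p = 0.0682). It was also lost without finishing replicates 5 and 6 (adjusted p = 0.132). For the cholesterol list the values were as follows. The camera adjusted p was 0.00354, with adjusted p = 0.68 with an estimated correlation and an exact permutation adjusted p of 0.0853. Of 27 unfolded protein response genes 1 rose, HERPUD1, and 0 fell (5 and 0 adjusted over the list alone). The HERPUD1 call, 0.54 ± 0.16 (adjusted p = 0.0458), was lost in 12 of 16 fits that left out 1 array (all but growing replicate 3 and finishing replicates 1, 3 and 4), with a highest adjusted p of 0.087. The list's camera adjusted p was 0.00246, with adjusted p = 0.717 with an estimated correlation and an exact permutation adjusted p of 0.161, and it was 0.0625 without finishing replicates 5 and 6.

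**Figure D3:**
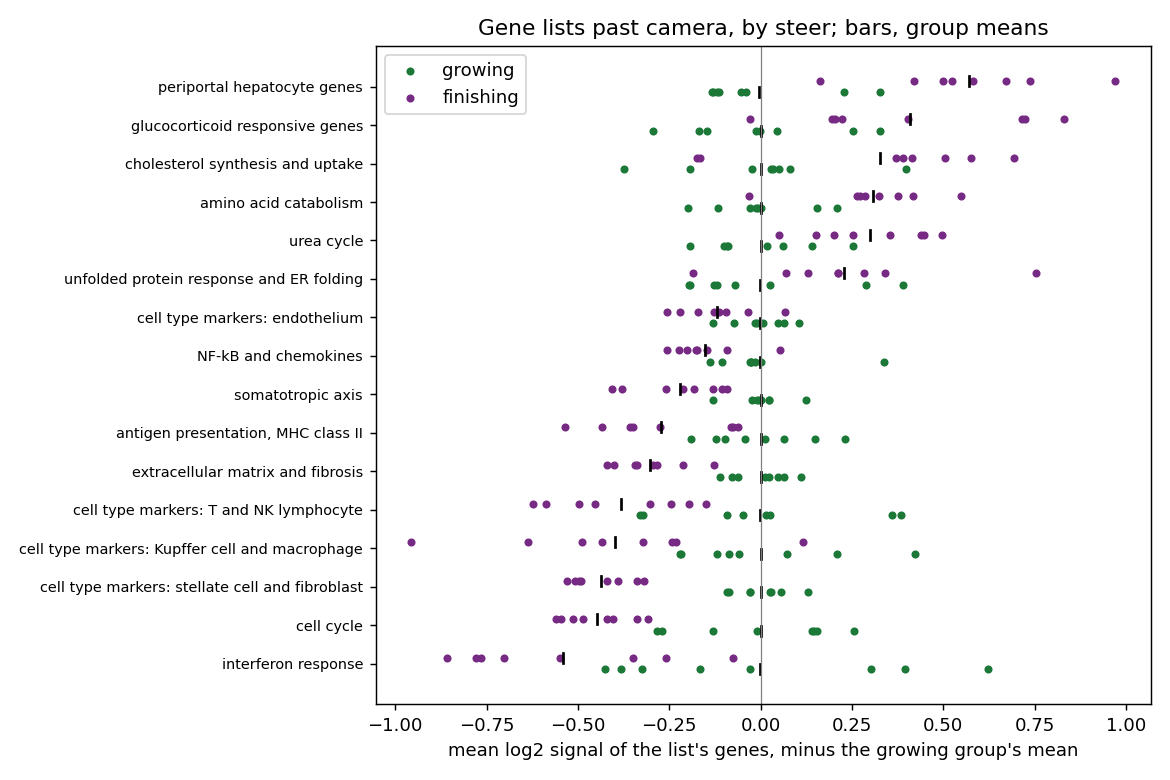
Mean log2 signal of the members of each list past camera, with the growing group's mean subtracted, each point a steer and black bars the group means of 8 steers. Stellate cell and fibroblast markers and extracellular matrix genes were lower in finishing steers by -0.437 and -0.303, and periportal genes were higher by 0.576, with a median over members of 0.23.

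Glutamate and glutamine genes moved in both directions. Of 21 measured members 4 rose and 1 fell (6 and 3 adjusted over the list alone). GOT1, cytosolic aspartate aminotransferase, rose by 1.34 ± 0.24 (adjusted p = 0.0041) and SLC38A3, a glutamine transporter, by 0.41 ± 0.09 (adjusted p = 0.0128), beside GLS2. The median change was -0.059 and the mean 0.115, so the median and mean differ in sign, and camera pointed upward with an adjusted p of 0.617. The list score, which is not set against other genes, was higher in finishing by 0.115 ± 0.029 (SE, exact permutation adjusted p = 0.00995), while fry gave an adjusted p of 0.37. The glutamate transporters SLC1A1 and SLC1A2 had differences of -0.39 ± 0.25 (adjusted p = 0.394) and 0.57 ± 0.21 (adjusted p = 0.122), and ARL6IP5, an interactor of SLC1A1, of -0.11 ± 0.07 (adjusted p = 0.342), none past the threshold.

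Other metabolic lists did not pass camera. By the exact permutation test of the score 4 of them were higher in finishing: gluconeogenesis and triglyceride and lipoprotein genes (both adjusted p = 0.00995), the tricarboxylic acid cycle (adjusted p = 0.0205) and propionate and one-carbon genes (adjusted p = 0.0385). None of the 4 passed fry (adjusted p = 0.0803, 0.772, 0.177 and 0.511 in that order). Their median changes were 0.17, 0.00275, 0.0503 and 0.0553, each below the mean (0.234, 0.15, 0.129 and 0.122). A score is a mean, so a few large rises can carry it. In the triglyceride list APOA4 rose by 1.98 and LPIN1 by 1.70, and in the propionate and one-carbon list GNMT rose by 1.85. The higher scores of these 2 lists therefore do not show a rise across their members. In gluconeogenesis 1 of 16 members rose and 1 fell, against 2 and 1 adjusted over the list alone (adjusted p = 0.328). Glycolysis and the pentose phosphate pathway had 1 of 16 up and 0 down, against 1 and 1 adjusted over the list alone (adjusted p = 0.227). For glycogen metabolism 1 of 10 rose and 0 fell, the same counts as adjusted over the list alone (adjusted p = 0.617), and the riser was GYS2, liver glycogen synthase, by 0.40 ± 0.10 (adjusted p = 0.0208, and 0.0592 without finishing replicates 5 and 6). Among fatty acid synthesis and desaturation genes 1 of 19 rose and 4 fell, against 3 and 7 adjusted over the list alone (camera adjusted p = 0.0972), and camera passed without growing replicate 8 (0.0451), finishing replicate 4 (0.0396) or finishing replicate 6 (0.0448), or without finishing replicates 5 and 6 together (0.0277), with adjusted p = 0.586 with an estimated correlation over all arrays. Beside FADS1, MLXIPL, a carbohydrate-responsive transcription factor, fell by 0.50 ± 0.09 (adjusted p = 0.00469), while the elongase ELOVL5 rose by 0.61 ± 0.13 (adjusted p = 0.0124). Triglyceride and lipoprotein genes went both ways, with 4 of 24 up and 3 down, against 5 and 4 adjusted over the list alone (adjusted p = 0.836), and MTTP, needed for lipoprotein assembly, fell by 0.49 ± 0.11 (adjusted p = 0.0118). Fatty acid oxidation had 1 of 25 up and 0 down, as adjusted over the list alone (adjusted p = 0.135, 0.0365 without finishing replicate 5 and 0.0277 without finishing replicates 5 and 6), and over all arrays adjusted p = 0.768 with an estimated correlation. Bile acid genes had 0 of 17 up and 2 down, as adjusted over the list alone (adjusted p = 0.0902), and camera passed without growing replicate 3 (0.028), growing replicate 4 (0.0302) or finishing replicate 4 (0.0378), with adjusted p = 0.717 with an estimated correlation over all arrays. Propionate and one-carbon genes had 1 of 16 up and 1 down, against 1 and 2 adjusted over the list alone (adjusted p = 0.617). In the tricarboxylic acid cycle 2 of 24 rose and 2 fell, as adjusted over the list alone (adjusted p = 0.229), with OGDH up by 0.88 ± 0.16 (adjusted p = 0.00469) and IDH2 lower by -0.34 ± 0.08 (adjusted p = 0.0173, and 0.0665 without finishing replicates 5 and 6), both cycle dehydrogenases. Mitochondrial electron transport (48 members), cytosolic ribosomal proteins (33) and the proteasome (30) had 0 members past the threshold over all probe sets or adjusted over the list alone (adjusted p = 0.617, 0.372 and 0.31).

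Signalling, stress and plasma protein lists did not pass camera either. Insulin and nutrient signalling had 0 of 20 up and 1 down, as adjusted over the list alone (adjusted p = 0.778), with a median of -0.034 and a mean of 0.032 that differ in sign, the faller being PRKAA1, an AMP-activated kinase subunit, by 0.37 ± 0.06 (adjusted p = 0.00409). Of 17 fetal and developmental genes MEST rose by 0.60 ± 0.09 (adjusted p = 0.00183) and H19 fell by 0.99 ± 0.22 (adjusted p = 0.0138), both imprinted genes, against 2 and 3 adjusted over the list alone (camera adjusted p = 0.617). Heat shock genes had 1 of 12 up and 1 down, against 4 and 1 adjusted over the list alone (adjusted p = 0.105), and camera passed without growing replicate 3 (0.0339), growing replicate 4 (0.0302) or finishing replicate 3 (0.025), with adjusted p = 0.762 with an estimated correlation over all arrays. Oxidative stress genes had 0 of 29 up and 2 down, against 1 and 3 adjusted over the list alone (adjusted p = 0.372). Xenobiotic and steroid genes had 1 of 29 up and 3 down, against 1 and 5 adjusted over the list alone (adjusted p = 0.617), with AHR, the aryl hydrocarbon receptor, lower by -0.70 ± 0.14 (adjusted p = 0.00954). Among acute phase genes 3 of 27 rose and 3 fell, against 6 and 3 adjusted over the list alone (adjusted p = 0.237), with SAA3 up by 1.03 ± 0.23 (adjusted p = 0.0134) and IL6R, the interleukin receptor, lower by -0.52 ± 0.07 (adjusted p = 0.000996). Complement and coagulation had 0 of 36 up and 3 down, against 0 and 6 adjusted over the list alone (adjusted p = 0.28). Immediate early genes had 0 of 20 past the threshold over all probe sets or adjusted over the list alone (adjusted p = 0.154, and 0.0377 without finishing replicate 2), and over all arrays adjusted p = 0.762 with an estimated correlation. Clock genes had 0 of 15 up and 1 down, as adjusted over the list alone (adjusted p = 0.617). Iron and trace metal genes had 0 of 16 past the threshold, against 1 up and 1 down adjusted over the list alone (adjusted p = 0.98). Pericentral hepatocyte genes had 1 of 14 up and 2 down, as adjusted over the list alone (adjusted p = 0.617), with LGR5, a Wnt-associated receptor, lower by -1.02 ± 0.18 (adjusted p = 0.00444).

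Markers of the remaining cell types did not pass camera. Among hepatocyte markers 0 of 17 rose and 1 fell, against 1 and 2 adjusted over the list alone (adjusted p = 0.252), the faller being AHSG, fetuin, by 0.46 ± 0.06 (adjusted p = 0.000996). B and plasma cell markers had 0 of 11 up and 1 down, as adjusted over the list alone (camera adjusted p = 0.0551), passing camera without growing replicate 7 (0.043) or 8 (0.0258) or finishing replicate 3 (0.026), 4 (0.0408) or 7 (0.0422). That list had a median of -0.139, with adjusted p = 0.433 with an estimated correlation over all arrays and 0.0249 by fry, and its faller was CD79A (-0.61 ± 0.09, adjusted p = 0.00135). Cholangiocyte markers had 0 of 11 up and 1 down, against 1 and 2 adjusted over the list alone (adjusted p = 0.481). Adipocyte markers had 0 of 12 up and 1 down, as adjusted over the list alone (adjusted p = 0.617), the faller being LPL, lipoprotein lipase, by 0.57 ± 0.10 (adjusted p = 0.00494). Neutrophil (14 members), erythroid (10) and skeletal muscle (11) markers had 0 past the threshold over all probe sets or adjusted over the list alone (adjusted p = 0.664, 0.286 and 0.394).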

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

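The weighing tests here were chosen after the results had been seen, except the splits of the arrays; the camera fits that left out each array in turn were planned, and their use to weigh the cell cycle genes was chosen afterwards. The 16 arrays were split at random into 8 and 8, with 100 splits in all, the real one included. The real split was the 1 split with as many probe sets higher (626) or lower (1151), the highest count in either direction among the others being 1. Chance can be excluded for those counts at this number of splits, which says nothing about what separates the groups. Of glutamate and glutamine genes 5 changed in the real split and at most 0 in the others, which adds nothing about these genes, since no other split called more than 1 probe set in all. Chance cannot be excluded for the 16 gene lists past camera, since 7 of the 100 splits gave as many and the highest other gave 19.

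Lower stellate cell, macrophage and T lymphocyte markers were weighed first. The stellate score fell more than the endothelial score (difference of scores -0.318 ± 0.0569 SE, exact permutation p = 0.000311). Both scores had been seen before this comparison was written. For stellate markers it argues against an equally lower share of all non-hepatocyte cells as the sole cause. Such a share joined by lower expression within stellate cells is not excluded. For macrophage and T lymphocyte scores against endothelium the difference did not pass (exact permutation p = 0.0577 and 0.0772), so for them an equal loss stays open. Finishing replicates 5 and 6 alone are argued against, since without them all 3 lists passed camera and their scores still differed by -0.444, -0.335 and -0.378 (exact permutation p = 0.000333, 0.0236 and 0.0117), though camera with an estimated correlation then gave p = 0.000185, 0.129 and 0.0606, so that macrophage and T lymphocyte markers did not pass it. A smaller share of these particular cells, or lower expression within them, may underlie the pattern, and the arrays do not separate these. Age, body weight and time on feed differ together between the groups, possibly with sampling date, and stay open, untested.

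Amino acid catabolism genes, higher by camera and by score but not by fry (adjusted p = 0.0996), were weighed next. Finishing replicates 5 and 6 alone are argued against, with a camera adjusted p of 0.0101 without them and a score higher by 0.264 (exact permutation p = 0.00633), though camera with an estimated correlation gave p = 0.261. A glucocorticoid or stress response around sampling may contribute, as glucocorticoid genes outside the amino acid list scored higher in finishing steers by 0.41 ± 0.142 (SE, exact permutation p = 0.0138). Within growing steers, however, r was negative and did not pass adjustment (r = -0.748, exact permutation p = 0.029, adjusted p = 0.116 over 4 relations, rho = -0.667, exact permutation p = 0.0831). Within finishing steers r was 0.351 (exact permutation p = 0.418, adjusted p = 0.418, rho = 0.333, exact permutation p = 0.428). Without the 2 steers farthest from their group's median glucocorticoid score r was -0.27 in growing and 0.0193 in finishing steers. Leaving these out narrows the range of that score, so it does not show whether a relation rests on them. A stress response that differed between the groups would coincide with growth phase in this design. The group difference therefore cannot tell this explanation apart from growth phase, and the relations within groups of 8 steers did not pass adjustment.

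Lower cell cycle genes were weighed last. A single array is argued against, since the list passed camera with the preset correlation in all 16 fits that left out 1 array (with all arrays adjusted p = 0.179 with an estimated correlation), with an exact permutation p of the score from 0.000155 to 0.000777. Fewer cycling T lymphocytes may contribute and cannot be told apart from less division of other liver cells, since the cell cycle score fell about as far as the T lymphocyte score (difference of scores -0.0666 ± 0.0998 SE, exact permutation p = 0.528), which does not show that they moved alike. Within growing steers the scores gave r = 0.553 (exact permutation p = 0.162, adjusted p = 0.324, rho = 0.69, exact permutation p = 0.0694). Within finishing steers r was 0.46 (exact permutation p = 0.248, adjusted p = 0.33, rho = 0.571, exact permutation p = 0.151). Without the 2 steers farthest from their group's median T lymphocyte score r was 0.0644 in growing and -0.0694 in finishing steers. Leaving these out narrows the range of that score, so it does not show whether a relation rests on them. Growth phase stays open, untested.

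A steer far from the rest of its group by Dixon's criterion was found in 10 of 276 groups of 8 values. A rate of about 1 group in 20 would give 13.8, but it assumes independent groups not picked by their p. These groups share the same steers and most genes were picked for a small p, so the count does not show that no steer stands apart. Growing replicate 4 accounted for 7 of the 10: PRODH2 at 6.47, PEMT at 9.71, BOLA-DRB3 at 10.5, HLF at 8.78, CTSS at 10.4, CD4 at 6.71 and the NF-kB and chemokine score at 6.38. Finishing replicate 5 accounted for FMO1 at 11.5 and HLF at 7.70, and growing replicate 5 for IL7R at 5.99.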

How the results depend on the processing

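Leaving out finishing replicates 5 and 6 together, and testing annotated probe sets only, were chosen after seeing the data. No called gene or list changed direction under the alternatives run. The count of probe sets higher in finishing went from 626 to 112, and that of probe sets lower in finishing from 1151 to 319, at an adjusted p below 0.01, with 3 glutamate and glutamine genes, and to 199 and 301 with a fold of at least 1.5, with 2 such genes, because fewer probe sets meet a stricter threshold. The rank-sum test gave 390 probe sets higher in finishing and 849 probe sets lower in finishing, and the cause was not tested. Fry passed 13 lists against 16. Without finishing replicates 5 and 6, 288 were higher and 654 lower with fewer arrays, and 876 of the 942 were among the original calls. Leaving out each array in turn gave 410 to 881 higher and 858 to 1324 lower, 14 to 19 lists and 5 to 6 glutamate and glutamine genes, with the count higher lowest without growing replicate 1 (410) and growing replicate 8 (415). With an estimated correlation 1 list passed. The estimate was above the preset 0.01 in most lists. Every list that lost its call had an estimate above the preset, from 0.0394 for the somatotropic axis to 0.582 for macrophage markers. An adjusted p also depends on the other lists. Gluconeogenesis, with an estimate below the preset (-0.0118) and no call to lose, went from a camera adjusted p of 0.328 to 0.586. How much of each loss came from the higher correlation was not tested. With the replicate number as a block 268 were higher and 642 lower, 863 of 910 shared. Same-number arrays gave correlations of -0.153 to 0.0406, and among finishing steers replicate 8 alone correlated best with its own number, so the numbers were not taken to pair steers. The alternative pseudocount was not run, the values being on a log scale. The 3 rescalings moved the median of all probe sets by -0.0197, -0.00208 and -0.0114. Of single genes and list medians under the alternatives, 4102 values kept their direction and side of the threshold, 404 lost the call and 33 gained one. Another 33 changed sign, all medians of lists that passed camera in neither setting. Arrays without detection calls leave signal over background unknown for dim genes.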

Other observations

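Of genes for making ribosomes, 41 of 105 measured members rose in finishing steers and 0 fell, while the other 64 did not pass. This theme was noticed among the risers and its list of 112 nucleolar and pre-ribosomal genes was written afterwards, so its test is a hypothesis on the data that prompted it, and the test was chosen after the result was seen. Over the 105, 103 had a positive change and the median was 0.36 on the log2 scale. UTP20, a pre-ribosomal RNA processing factor, rose by 1.21 ± 0.18 (SE, n = 8 per group, limma adjusted p = 0.00143), GNL3, nucleostemin, by 1.14 ± 0.23 (adjusted p = 0.00922) and TSR1 by 0.86 ± 0.17 (adjusted p = 0.00688), all chosen after their values were seen.

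Ribosome biogenesis genes may stand above other genes in finishing livers. Camera gave p = 1.22e-30 with the preset correlation and p = 0.0446 with an estimated correlation of 0.528, and the list score differed by 0.387 (exact permutation p = 0.00202). Without both finishing arrays that stood apart (replicates 5 and 6) 12 members rose. Camera then gave p = 1.77e-25 with the preset correlation but p = 0.0589 with an estimated correlation over fewer arrays, and the call was lost. The score then differed by 0.306 (exact permutation p = 0.00733). The hypothesis stays open, since the list was written from a theme seen in these data and the p-values are not adjusted for that choice.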
